A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

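Chromatin immunoprecipitation was read on 2-colour Agilent tiling arrays of the yeast genome, with 1 array per sample and 8 arrays in all. Per the labels' protocols, IP DNA was labelled with Cy5 (red) and input DNA with Cy3 (green) on every array, with no dye swap, from cells grown in rich medium. Groups were taken from the sample titles as wild type or rtr1 deletion, with the H14 antibody or the H3K36me3 antibody, 2 replicates in each of the 4 groups.

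Each array had 243504 spots, of which 237908 were probes other than controls, 45 to 60 nt long with a median spacing of 44 bp. Per the file headers, the deposited processed intensities were made with Agilent Feature Extraction by background subtraction with spatial detrending, multiplicative detrending and a linear dye normalisation of each channel, with no lowess term. Version 10.5.1.1 was used for 6 of the arrays and 11.5.1.1 for both H14 replicate 2 arrays, per the file headers, and the submitters' processing notes name 10.5.1.1. The deposited raw mean and background intensities were used only for an alternative background correction. The files also give a log10 ratio of red over green made by the same software, per the file headers. The authors' deposited series matrix holds log2(IP/input) of the same arrays. Set against the scanner log10 ratio, its columns rose with a positive slope and rank correlations from 0.986 to 0.999, and their medians lay between -0.0017 and 0.0098. How its columns were centred is not given in the sources used here. The signal over background was high, with at least 98.7% of the probes of each array above background in the input channel. The number of arrays limits the precision.

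Here the log2 of the processed red over green intensity was taken per probe and centred on each array's median over the kept nuclear probes, with no loess or quantile step, since much of a chromatin array carries signal. Control spots, probes with an outlier flag on any array and probes whose input was not well above background on all 8 arrays were left out, which left 229160 probes. Probes were placed by the gene names, distances to the start codon and coordinates that the newer array grids in the files give. The genome build behind them is not given in the sources used here, and 112 probes had no position. The coding length of each ORF came from the reference gene table of assembly R64. Of its 6021 protein-coding genes, 5853 (97.2%) were placed, and 98.6% of the distances between neighbouring start codons matched the files' within 5 bp. The plan to keep only probes with a single match in a genome sequence could not be carried out without one. In an alternative, 378 probes (0.159%) that share a stretch of 30 nt with a probe elsewhere were left out instead. The number of columns of per-sample values not used was 0.

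An ORF's value was the mean of its probes, at least 3, which gave 5654 ORFs with a median of 25 probes. The 5′ minus 3′ value was the mean over the first part of the ORF minus the mean over the last, each part covering the same share of the coding length and holding at least 3 probes, which gave 4972 ORFs. Profiles were medians over ORFs in 5 regions with at least 2 probes, the flanks being 250 bp without probes inside another ORF. Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over all 8 arrays with 1 mean per group, 4 residual degrees of freedom and a shared spread, with Benjamini-Hochberg adjustment at 0.05. The shared spread includes the H14 arrays in the H3K36me3 test, so a fit on each antibody's own 4 arrays was an alternative. Of 28 gene lists, 25 had at least 5 measured ORFs and were tested with camera at an inter-gene correlation of 0.01, and with an estimated correlation as an alternative. That correlation was estimated from the residuals of all 8 arrays, so a list has the same value for both antibodies. It was not estimated on the 4 arrays of 1 antibody. Lists of snoRNA genes and intron-containing genes were not analysed here, and the mitochondrial genome was described by its values.

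These tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except those said below to have been chosen after. For each antibody, the rule took up to 10 ORFs in each direction among those passing that went the same way in both pairs or, where too few passed, the 5 of that direction with the largest difference, named as not passing. For the 5′ minus 3′ value and the interaction it took 5 in each direction. It added RTR1, the CTD enzyme and Set2-Rpd3S lists, from which examples are given, and the 3 leading members of each list called by camera, from which at least 1 is given. ORFs that overlap another by over 50% of their length were skipped.

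The scan dates in the headers put the arrays in 4 batches, each holding the wild-type and the rtr1 array of one antibody and replicate number, so the scan batch and the replicate number are the same block. The deviations of same-numbered arrays from their group means correlated across ORFs at 0.366 for H14 and -0.0494 for H3K36me3. In this balanced design the block leaves each difference as it is and changes only its error.

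The tests were tried on simulated data made from the real ORFs and group means. Each ORF was given 1 spread for all arrays, with errors drawn independently. The real H14 differences had an SD over ORFs of 0.153 in the replicate 1 pair and 0.355 in the replicate 2 pair. The H14 recovery rates that follow may therefore be too high. At a true log2 difference of 1, limma recovered 82.1% of 67 changed ORFs for H14 and 85.1% of 67 for H3K36me3, and at 0.5, 23.9% and 17.9%. Unchanged ORFs made up 13 of the calls (8.67%) for H14 and 11 (7.64%) for H3K36me3 in these runs, a larger share than the threshold of 0.05 aims at. For the 5′ minus 3′ value it recovered 38.8% (H14) and 43.3% (H3K36me3) of 67 at 1, 93.9% of 66 at 2 for each, and 0% of 67 at 0.5 for each, with 4 (4.35%) and 7 (7.14%) calls of unchanged ORFs. A shift of 0.4 given to the glycolysis list was called for both antibodies, with 0 other lists called. The simulated errors were independent between ORFs, whereas the correlation estimated in the real data was 0.787 for the glycolysis list. The run therefore does not show how the list test fares when genes vary together. Alternatives covered background correction, normalisation within and between arrays, scaling, centring, probe filters, probe summaries, the block, the arrays in the fit, the authors' log2 values, the eBayes settings and leaving out each array. Files were read with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3) and the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9.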

Results

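The arrays measured where 2 marks of transcription elongation lay along the genome of budding yeast, Saccharomyces cerevisiae, in wild-type cells and in cells lacking RTR1. RTR1 encodes a phosphatase of the C-terminal domain (CTD) of RNA polymerase II, and the question was how its loss bears on CTD phosphorylation and on the histone mark that follows elongating polymerase. The antibody H14 recognises the CTD phosphorylated at serine 5, a form of the polymerase found early in genes. The second antibody recognises H3K36me3, the trimethylation of histone H3 that Set2 places over transcribed gene bodies. Each of the 4 groups (wild type or rtr1 deletion with either antibody) had 2 replicates, so 8 arrays were read, each comparing immunoprecipitated DNA (IP) with input DNA. The 8 arrays limit the precision of every value. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Same-numbered wild-type and rtr1 arrays of one antibody were scanned in the same batch, and each such pair is therefore also a within-batch comparison. All values are log2(IP/input) centred on each array's median unless stated otherwise, and differences are rtr1 minus wild type. Each standard error (SE) of a difference comes from the spread shared by all 8 arrays, so an H3K36me3 SE also holds the H14 spread.

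The targeted gene was examined first, in the input channel, where a deletion removes the DNA. RTR1 lies on chromosome V, and its 16 probes spanned positions 450560 to 451230 in the files' coordinates. Relative to the array median, the log2 input at RTR1 was 0.06 and -0.19 on the wild-type H3K36me3 arrays and -3.99 and -4.37 on the rtr1 H3K36me3 arrays. It was -0.14 on wild-type H14 replicate 1, where 2 of the 16 probes carried an outlier flag, and -5.19 and -7.50 on the rtr1 H14 arrays. The library labelled wt H14 replicate 2 stood at -2.23, below the other wild-type arrays and above all 4 rtr1 arrays. By the input its label is therefore only partly borne out, and any H14 direction below rests in part on it. In the IP channel, RTR1 stood at 0.33 and 0.56 on the wild-type H3K36me3 arrays and -0.60 and -0.58 on the rtr1 H3K36me3 arrays. On the latter, URA3 fell to -4.40 and -7.50 in that channel. The H14 arrays had -0.21 and -1.41 at RTR1 in wild type and -2.59 and -7.00 in rtr1. The rtr1 label is thus only partly borne out for the H3K36me3 IP samples and H14 replicate 1, for a cause not tested. The ratio at RTR1 itself (a difference of 2.92 for H3K36me3 and 1.37 for H14) sets the remaining IP signal against almost no input DNA on the rtr1 side. It gives no level of either mark. LEU2, MET17 and URA3, often deleted in laboratory strains, had very low input on all 8 arrays (at URA3, between -7.15 and -10.4), while LYS2 lay near the array median.

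**Figure D1:**
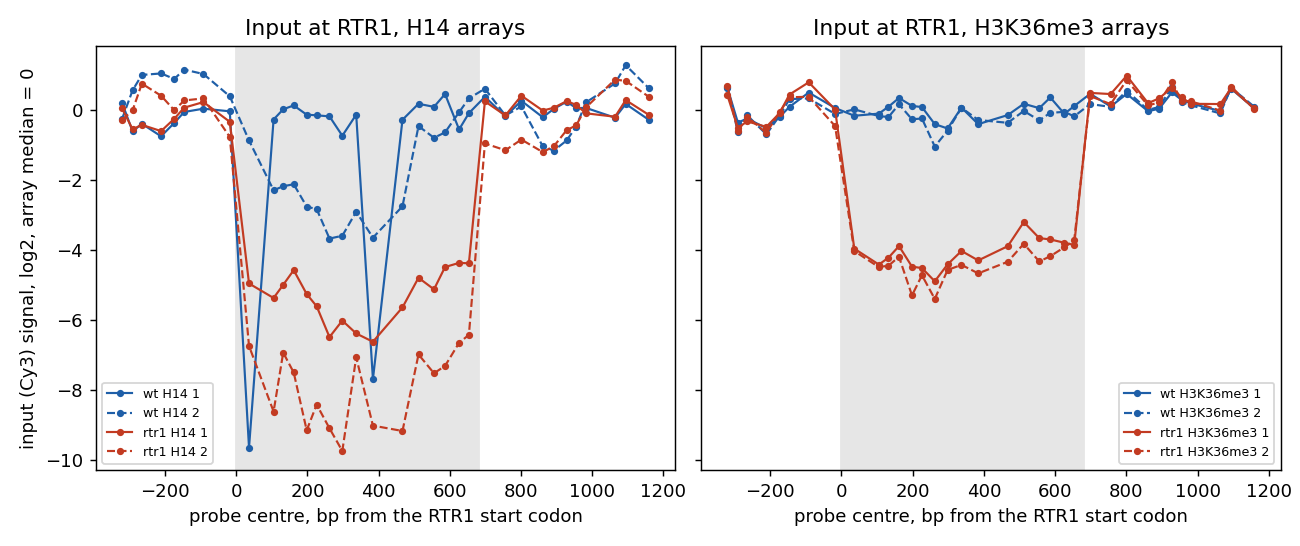
Input (Cy3) signal of each probe at and around RTR1, as log2 relative to the array's median, against the distance of the probe's centre from the start codon in bp, with 1 line per array, H14 and H3K36me3 arrays in separate panels and the coding sequence shaded. Over the coding sequence the medians of the rtr1 arrays lie between -3.99 and -7.50 and that of the library labelled wt H14 replicate 2 at -2.23, while 2 outlier-flagged probes lie far down on wild-type H14 replicate 1.

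For the H14 antibody, the largest differences over open reading frames (ORFs) that went the same way in both pairs, the deleted RTR1 aside, were the negative ones at YCR006C, TAH1 and YCH1 and the positive one at RPB10. RPB10, which encodes a small subunit shared by the nuclear RNA polymerases, stood at -0.13 ± 0.31 (SD, n = 2) in wild type and 0.77 ± 0.09 in rtr1, a difference of 0.90 ± 0.17 (SE). Next among the higher values came TOS6 with 0.79 ± 0.24, CYB5 (cytochrome b5) with 0.71 ± 0.30, the phosphate transporter gene PHO84 with 0.71 ± 0.58 and EGT2 with 0.61 ± 0.17. Lower in rtr1 were YCR006C at -1.04 ± 0.34, TAH1 at -1.01 ± 0.41, YCH1 at -0.91 ± 0.37, RSO55 at -0.88 ± 0.52 and BAT2, a branched-chain aminotransferase gene, at -0.86 ± 0.19. None of these passed limma's test after Benjamini-Hochberg adjustment over 5654 ORFs (smallest adjusted p 0.866). The count of ORFs passing was 0, and 217 had an unadjusted p under 0.05 (82 higher, 135 lower) where chance gives 282.7. The count was also 0 with the scan batch as a block and 0 on the 4 H14 arrays alone, and 59 (11 higher, 48 lower) without wild-type H14 replicate 1.

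The genes of the CTD phosphorylation cycle and of the H3K36 methylation pathway showed no H14 difference past the threshold. Among 17 measured CTD kinase, phosphatase and isomerase genes, RTR1 aside, ESS1 (a prolyl isomerase of the CTD) had the most negative difference at -0.66 ± 0.33, TFB3 of TFIIH had -0.25 ± 0.15, and the phosphatase genes GLC7 and SSU72 had 0.22 ± 0.11 and -0.15 ± 0.74. The kinase genes KIN28 and CTK1 had -0.09 ± 0.13 and 0.12 ± 0.10, and the phosphatase gene FCP1 had 0.01 ± 0.13. Of the 18 genes of the Set2 and Rpd3S pathway, the histone deacetylase gene RPD3 had 0.30 ± 0.20, CDC73 of the Paf1 complex had -0.22 ± 0.17 and SET2 had 0.13 ± 0.12. Adjusted over the list alone, 0 genes passed in both of these lists, and 1 of the 12 RNA polymerase II subunit genes, RPB10, passed in its own.

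Of the 25 gene lists tested on H14, hexose transporters (median difference 0.20) and cell wall genes (0.07) came closest to the threshold, both with camera's adjusted p at 0.0974. Their medians were -0.02 and 0.42 in the replicate 1 and replicate 2 pairs for hexose transporters, and -0.06 and 0.29 for cell wall genes. Glycolysis genes (-0.11 and 0.31), histone genes (-0.07 and 0.30) and amino acid biosynthesis genes (-0.15 and 0.19) likewise had opposite signs in the 2 pairs, as did 18 of the 25 lists. Camera called 0 lists, with 6 at an unadjusted p under 0.05. It also called 0 with an estimated correlation (smallest adjusted p = 0.921). It called 10 with scaling by the median absolute deviation (MAD; 9 higher, 1 lower), 6 with quantile normalisation (5 higher, 1 lower), 6 with a normexp background correction, all higher, 2 on the 4 H14 arrays alone and 1 with loess, all higher. With the scan batch as a block it called 3, hexose transporters (adjusted p 0.0227), genes under Nrd1-Nab3 control (0.0397; median 0.10) and translation factors (0.0397; median 0.08). Without 1 H14 array it called 5 (wild-type replicate 1 left out), 12 (the library labelled wt H14 replicate 2), 15 (rtr1 replicate 1) and 7 (rtr1 replicate 2). The list median and camera's direction differed in sign for 3 lists, CTD enzymes, RNA polymerase II subunits and general stress genes.

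For H3K36me3, the lists of glycolysis and fermentation genes and of histone genes had the highest median differences of the 25 gene lists. At the glyceraldehyde-3-phosphate dehydrogenase gene TDH3 the mean was -0.80 ± 0.11 (SD, n = 2) in wild type and 0.37 ± 0.09 in rtr1, a difference of 1.17 ± 0.43 (SE), with 1.31 and 1.03 in the 2 pairs. The alcohol dehydrogenase gene ADH1 had 0.80 ± 0.31, TDH2, a second gene for the TDH3 reaction, had 0.73 ± 0.29, and ILV5 of branched-chain amino acid synthesis had 0.78 ± 0.39. With TDH3, ADH1 and ILV5, YPL080C (0.78 ± 0.13) and MRPL33, a mitochondrial ribosomal protein gene (0.76 ± 0.15), had the 5 most positive differences, the deleted RTR1 aside. Lower in rtr1 were GCV2 of the glycine cleavage system (-0.62 ± 0.22, and -0.62 in each pair), PRM7 (-0.58 ± 0.20), MTD1 of one-carbon metabolism (-0.57 ± 0.21), the IMP dehydrogenase gene IMD2 (-0.50 ± 0.15) and EMP65 (-0.49 ± 0.14), which lies beside RTR1. None passed limma's test (smallest adjusted p 0.999). The count was 0 of 5654 ORFs, with 201 at an unadjusted p under 0.05 (165 higher, 36 lower). It was 0 with the scan batch as a block and 1, the deleted RTR1, on the 4 H3K36me3 arrays alone.

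Tested as groups, 8 of the 25 lists were called by camera for H3K36me3, 7 higher and 1 lower, and 0 were called with an estimated correlation (smallest adjusted p = 0.931 with that correlation). Glycolysis and fermentation rose by a median of 0.46 over 17 genes (0.48 and 0.50 in the pairs; 16 higher in both). Its adjusted p was 1.77e-06, and its p with an estimated correlation was 0.190. The correlation behind this p, 0.787, and those of the other lists come from all 8 arrays, the H14 arrays included. The histone genes rose by 0.39 over 8 genes (0.33 and 0.48 in the pairs; 7 higher in both), with an adjusted p of 6.91e-05 and a p of 0.111 with an estimated correlation. Among them were the histone H3 genes HHT1 (0.67 ± 0.26) and HHT2 (0.66 ± 0.15) and the H2A.Z gene HTZ1 (0.42 ± 0.16). TDH2 and TDH3, HHT1 and HHT2, and SSA1 and SSA2 are similar in sequence, so their probes may bind DNA from either copy, which was not tested. Their values also rest on few probes against a median of 25 per ORF. TDH3 had 5, TDH2 7, HHT1 5, HHT2 3, SSA1 12 and SSA2 13. Adjusted over the list alone, 1 histone gene (HHT2) and 1 CTD enzyme gene (the deleted RTR1) passed, and 0 in the other 23 lists.

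The respiratory chain list rose by 0.16 over 35 genes (adjusted p 0.00861; p = 0.238 with an estimated correlation). NDE1, a mitochondrial NADH dehydrogenase gene, had 0.44 ± 0.21 and COX8 had 0.38 ± 0.22. The mitochondrial ribosome list rose by 0.12 over 67 genes (adjusted p 0.00861; p = 0.268 with an estimated correlation), and in it MRP35 had 0.46 ± 0.15 and MRPL6 0.44 ± 0.12. Heat shock chaperones rose by 0.14 over 24 genes (adjusted p 0.0494; p = 0.191 with an estimated correlation). The Hsp70 genes SSA2 and SSA1 had 0.57 ± 0.23 and 0.38 ± 0.17, and the mitochondrial disaggregase gene HSP78 had 0.38 ± 0.16. The proteasome list rose by 0.12 over 33 genes (adjusted p 0.0494; p = 0.577 with an estimated correlation), with PRE9 at 0.26 ± 0.14. The list of G1/S and S phase genes rose by 0.09 over 28 genes (adjusted p 0.0494; p = 0.210 with an estimated correlation). The cyclin gene PCL1 had 0.65 ± 0.20 and the ribonucleotide reductase gene RNR1 had 0.55 ± 0.14. The subtelomeric families were the list called lower, with a median of -0.04 over 22 genes (adjusted p 0.00210; p = 0.148 with an estimated correlation; 9 lower in both pairs). COS6, with 3 probes, had -0.26 ± 0.10, TIR4 -0.24 ± 0.13 and FLO1 -0.23 ± 0.16. With the scan batch as a block 9 lists were called. G1/S and S phase was lost (adjusted p 0.127), as it was in 16 of its 26 other settings (some of which give the same fit), and cell wall (0.0157; median 0.18) and phosphate response (0.0159; median 0.19) were gained (adjusted p = 0.931 for both with an estimated correlation). The count was 4 without wild-type H3K36me3 replicate 1 or without rtr1 H3K36me3 replicate 2, and 5 without rtr1 H3K36me3 replicate 1 or either wild-type H14 array, without the background filter or with the authors' values. Heat shock and proteasome calls were lost without any one of the 4 H3K36me3 arrays (adjusted p up to 0.180 and 0.202), while glycolysis, histones and subtelomeric families remained called whichever array was left out. The respiratory chain call was lost without wild-type H3K36me3 replicate 1 (adjusted p 0.0972) and without rtr1 H3K36me3 replicate 2 (0.0631). That of the mitochondrial ribosome was lost without rtr1 H3K36me3 replicate 1 (0.0831) and with loess (0.0557).

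Among the lists not called for H3K36me3, general stress genes had a median difference of 0.08 (adjusted p 0.0566) and amino acid biosynthesis genes 0.11 (0.0787). RNA polymerase II subunit genes had 0.11, hexose transporters 0.09, ribosome biogenesis 0.08 and translation factors 0.08. The Set2 and Rpd3S pathway had 0.07, glucose-repressed genes 0.04 and genes with known cryptic promoters -0.00456. SET2 itself had 0.14 ± 0.12, POB3 of the FACT complex 0.18 ± 0.10, EAF3 of Rpd3S 0.16 ± 0.11 and SSU72 0.31 ± 0.74. Ribosomal protein genes (0.08), sporulation genes (0.02), CTD enzymes (0.02), genes under Nrd1-Nab3 control (0.15), mating genes (0.04) and ergosterol biosynthesis genes (0.08) had a positive median with a negative camera direction. Camera compares a list with the other ORFs, whose own values lay above 0 (median over all ORFs 0.06). The medians of 24 of the 25 lists were above 0 in both pairs.

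**Figure D2:**
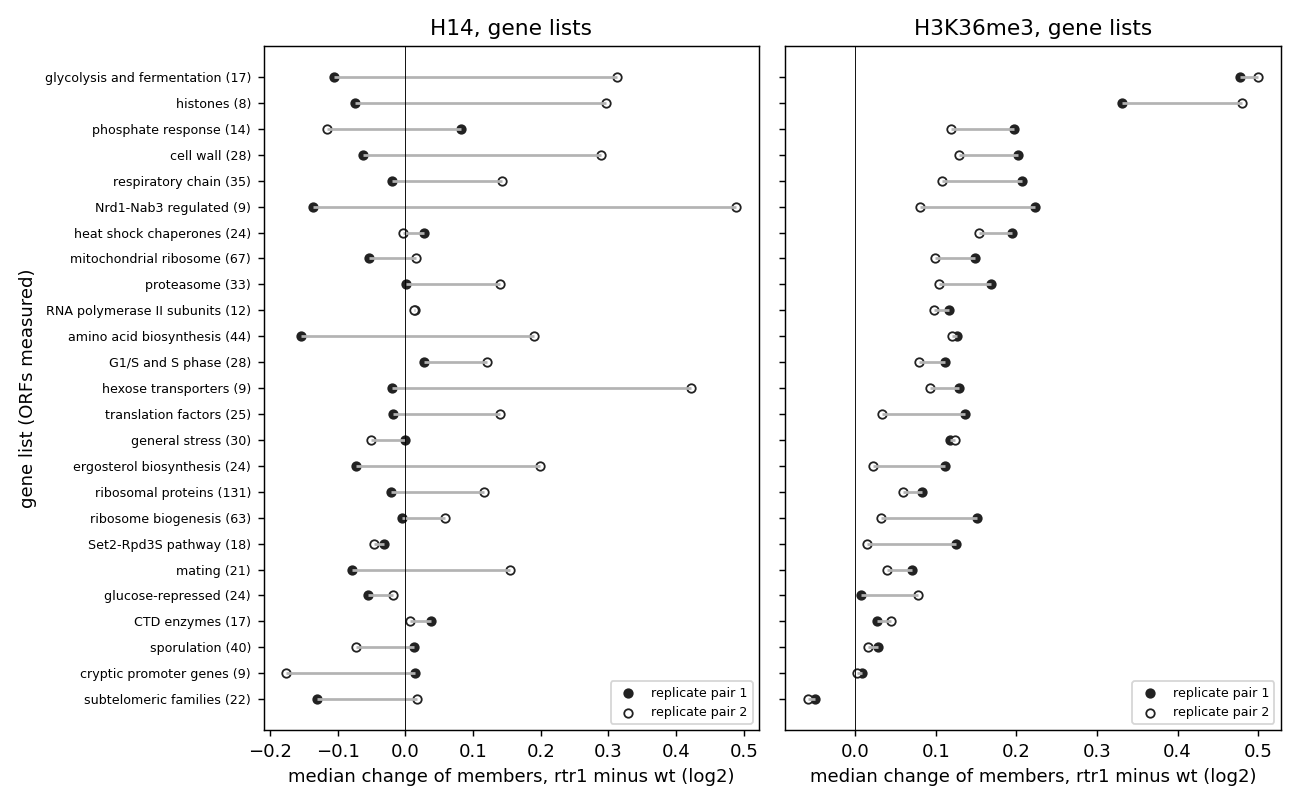
Median log2 difference (rtr1 minus wild type) over the members of each gene list (number of measured ORFs in brackets) for H14 and H3K36me3, with the replicate 1 pair as filled and the replicate 2 pair as open points joined by a line. For H3K36me3, glycolysis and fermentation (0.48 and 0.50) and histones (0.33 and 0.48) stand farthest above 0 in both pairs, while 18 of the 25 H14 lists have opposite signs in the 2 pairs.

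The 5′ minus 3′ value, the mean over the first part of an ORF minus that over its last part of equal length, asks whether the mark moved along genes, and it does not depend on how an array was centred. For H3K36me3 the genes with the most negative differences were ADE17 of purine synthesis, the pyruvate kinase gene CDC19, the serine hydroxymethyltransferase gene SHM2, the glycogen branching enzyme gene GLC3 and the Hsp70 gene SSA2. At ADE17 the value was 0.05 ± 0.02 (SD, n = 2) in wild type and -1.47 ± 0.14 in rtr1, a difference of -1.53 ± 0.21 (SE), with -1.64 and -1.42 in the 2 pairs. CDC19 had -0.07 ± 0.06 in wild type and -1.49 ± 0.02 in rtr1, a difference of -1.42 ± 0.30. SHM2 had -1.28 ± 0.26, GLC3 -1.16 ± 0.25 and SSA2 -1.16 ± 0.21. The most positive differences were smaller, from 0.82 ± 0.27 at NUT2, a Mediator subunit gene, through ORT1 (0.81 ± 0.22), ADD37 (0.79 ± 0.37) and TAD2 (0.72 ± 0.21) to the translation factor gene TIF11 (0.72 ± 0.26).

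None of these passed limma's test over 4972 ORFs in the fit of all 8 arrays (adjusted p 0.136 at ADE17). The count was 0, with 222 at an unadjusted p under 0.05 (47 higher, 175 lower) where chance gives 248.6. It was 0 with the scan batch as a block and 2, ADE17 and CDC19, both lower, on the 4 H3K36me3 arrays alone, and 1, ADE17, with quantile normalisation or MAD scaling. Without a wild-type H14 array, whose spread enters the shared error, 15 ORFs passed (either array gives one and the same fit), among them ADE17, CDC19, SHM2, GLC3, SSA1 and SSA2. Over all ORFs the median difference was -0.10 (-0.12 and -0.09 in the pairs) and -0.18 with a normexp background correction, and 45.4% of ORFs were lower in both pairs against 16.0% higher in both.

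For H14 the 5′ minus 3′ differences reached 1.23 ± 0.58 at UPS1, 1.21 ± 0.40 at TFS1, 1.03 ± 0.67 at SKP1, 1.00 ± 0.33 at PRP18 and 0.98 ± 0.24 at the meiotic nuclease gene SPO11. The most negative were -1.33 ± 0.52 at REV7 of translesion DNA polymerase zeta, -1.27 ± 0.56 at the G1/S repressor gene NRM1, -1.20 ± 0.44 at the sirtuin gene HST3, -1.16 ± 0.36 at CYC2 and -1.15 ± 0.40 at MRPS12. At each of these genes the replicate 2 pair gave the larger difference, with 2.04 at UPS1 and -2.63 at REV7 against 0.43 and -0.02 in the replicate 1 pair. The count passing limma's test was 0 (smallest adjusted p 0.611), with 365 at an unadjusted p under 0.05 (83 higher, 282 lower), 0 with the block and 0 on the 4 H14 arrays alone. Without wild-type H14 replicate 1 the count was 1212 (473 higher, 739 lower), and the library labelled wt H14 replicate 2 then alone stands for its group. The median over ORFs was -0.06, with -0.06 and -0.07 in the pairs.

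Along the average gene, H3K36me3 was lowest upstream of the start codon, higher in the first part and highest over the middle and last parts of ORFs on each of the 4 arrays. After the stop codon it was lower again (-0.41 and -0.49 in wild type, -0.39 and -0.37 in rtr1), though above the first part. In the last part of ORFs its median was 0.37 and 0.40 in wild type and 0.50 and 0.48 in rtr1, and the median over ORFs of each ORF's own difference was 0.14 and 0.10 in the 2 pairs. In the middle part it was 0.37 and 0.35 in wild type and 0.36 and 0.34 in rtr1, and in the first part -0.62 and -0.61 against -0.58 and -0.58. Upstream the H3K36me3 median was -1.18 and -1.28 in wild type and -1.14 and -1.16 in rtr1. The median of each ORF's own difference was 0.04 and 0.11 upstream and 0.02 and 0.12 downstream. In the replicate 2 pair both flanks thus differed by more than the last part. H14 upstream of ORFs was -0.13 and -0.20 in wild type and -0.05 and -0.22 in rtr1, and in the first part -0.02 and 0.06 in wild type and -0.06 and 0.00 in rtr1. The wild-type medians were 0.03 and 0.06 in the middle part and 0.01 and 0.07 in the last. By these medians over all ORFs H14 had no peak in the first part on either wild-type array. The early position of Ser5 phosphorylation was thus not seen in them. The wild-type profile over the ORFs with high H14 alone was not examined. In the 250 bp downstream of ORFs it was 0.08 and 0.07 in wild type and 0.21 and 0.09 in rtr1, and the median of each ORF's own difference was 0.10, which turned to -0.045 with a normexp background correction. No test was made of these medians, and the H3K36me3 value in the last part, 0.12 on average, lay between 0.07 and 0.19 over the other settings.

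**Figure D3:**
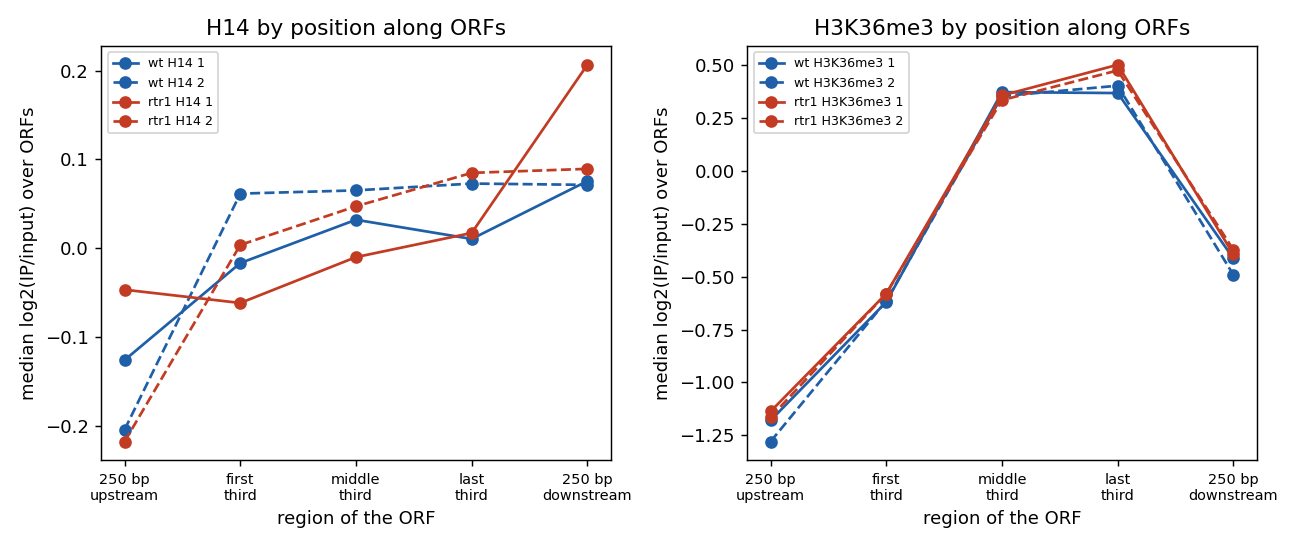
Median log2(IP/input) over ORFs in 5 regions (250 bp upstream, first, middle and last part of the ORF, 250 bp downstream) with 1 line per array and H14 and H3K36me3 in separate panels on different scales. The rtr1 H3K36me3 arrays lie above the wild-type arrays in the last part of ORFs (0.50 and 0.48 against 0.37 and 0.40). They also lie above them upstream, in the first part and downstream, but not in the middle part.

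The difference between the antibodies' rtr1 effects was examined as the interaction of the design. TOS6 (0.86 ± 0.34), PRM7 (0.83 ± 0.28), RPB10 (0.68 ± 0.23), TAF10 of TFIID (0.67 ± 0.21) and MOH1 (0.66 ± 0.15) had the largest excess of the H14 over the H3K36me3 difference. TAH1 (-1.44 ± 0.58), YLR236C (-1.12 ± 0.44), TDH3 (-1.09 ± 0.60), YCH1 (-1.08 ± 0.53) and the prolyl isomerase gene FPR1 (-1.04 ± 0.36) had the largest excess the other way, the deleted RTR1 aside. None passed (limma, 0 of 5654 ORFs; smallest adjusted p 0.986; 166 at an unadjusted p under 0.05, 24 higher and 142 lower; 0 with the scan batch as a block). Camera called 0 of the 25 lists, with 6 at an unadjusted p under 0.05 and the smallest adjusted p, 0.0715, at glycolysis and at genes under Nrd1-Nab3 control. With the block it called 2, the same lists (adjusted p 0.000248 and 0.0378), and with an estimated correlation 0 (smallest adjusted p = 0.979).

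Across 5654 ORFs the H14 and H3K36me3 differences had a Pearson's r of 0.105 and a Spearman's rho of 0.0636, and r was 0.239 with loess and 0.230 with MAD scaling. The lowest r over the settings other than leaving out each array was 0.0840. This is a correlation across genes, which are not independent replicates. It and the values below include the deleted RTR1, whose ratio gives no level of either mark. RTR1 had H3K36me3 differences of 2.975 and 2.864 and H14 differences of 2.49 and 0.25 in the pairs. Between the replicate 1 pairs r was 0.187 and between the replicate 2 pairs -0.0326, with 0.0737 and 0.0930 for the crossed pairs. Without wild-type H14 replicate 1 r was 0.00318, and without the library labelled wt H14 replicate 2 it was 0.231; without rtr1 H14 replicate 2, wild-type H3K36me3 replicate 1 or rtr1 H3K36me3 replicate 1 it was 0.0284, 0.0513 and 0.0430. For H3K36me3 the 2 pairs' own differences correlated at 0.255, with 46.1% of ORFs higher in both and 15.9% lower in both, whereas the H14 pairs correlated at 0.00107. The SD of the H14 differences over ORFs was 0.153 in the replicate 1 pair and 0.355 in the replicate 2 pair, against 0.201 and 0.183 for H3K36me3. Among the H14 arrays, the library labelled wt H14 replicate 2 correlated with wild-type replicate 1 at 0.669, while wild-type and rtr1 replicate 1 correlated at 0.897.

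**Figure D4:**
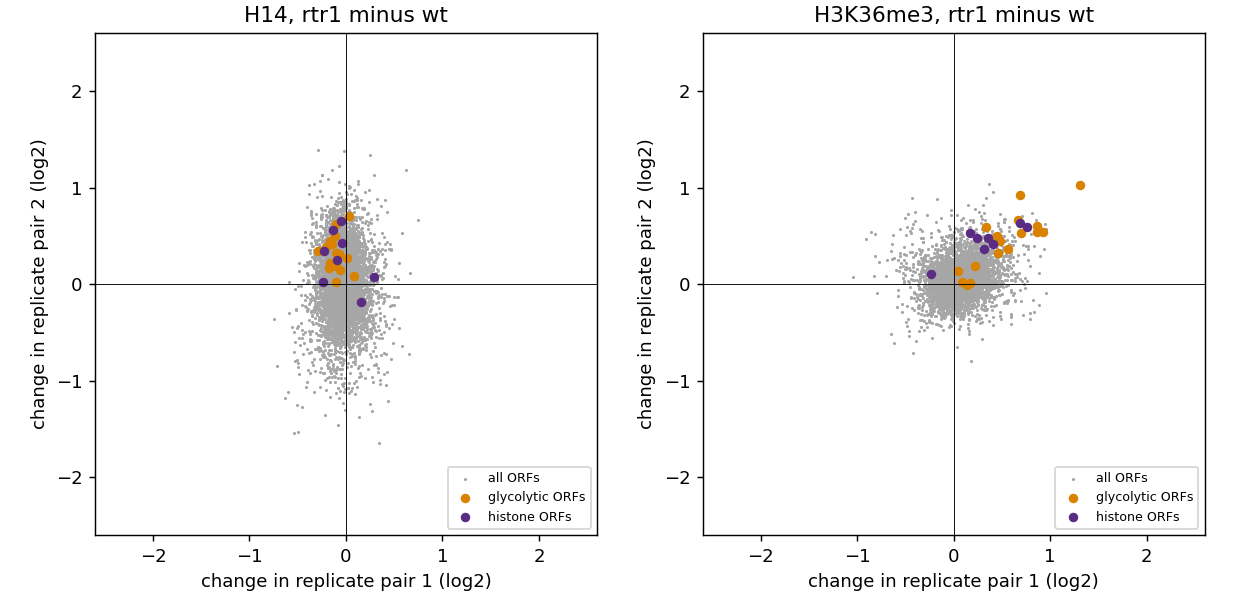
Log2 difference (rtr1 minus wild type) of each ORF in the replicate 1 pair against the replicate 2 pair, for H14 and for H3K36me3. The H3K36me3 differences of the 2 pairs correlate at 0.255 across ORFs, the H14 differences at 0.00107. The deleted RTR1 is not drawn but is included in these correlations.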

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

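Chosen after the results were seen were the GC correction, leaving out scan batch 4, the repeat probes or RTR1, and every setting of the profile medians, the 5′ minus 3′ medians and the H3K36me3 5′ minus 3′ lists. The counts of ORFs stayed at 0 for H14, for its 5′ minus 3′ value and for the interaction in each setting that kept all arrays, and with scan batch 4 left out. The replicate block, which is also the scan batch block, gave 0 ORFs in each test, 3 H14 lists, 9 H3K36me3 lists and 4 H3K36me3 5′ minus 3′ lists, and the numbers share only that batch, not a stated culture. H3K36me3 ORFs numbered 1 (RTR1) on its own 4 arrays and 1 with batch 4 left out. H3K36me3 5′ minus 3′ ORFs numbered 1 with quantile normalisation, 1 with scaling by the median absolute deviation (MAD), 2 on its own 4 arrays and 2 without batch 4. H14 lists numbered 6 with normexp, 1 with loess, 6 with quantile, 10 with MAD scaling, 2 on its own arrays and 2 without batch 4. H3K36me3 lists numbered 12 with quantile (11 higher, 1 lower), 10 with loess, on its own arrays and without batch 4, 5 without the background filter, 5 with the authors' values and 0 with an estimated correlation; glycolysis, histone and subtelomeric lists were lost only there. Its 5′ minus 3′ lists numbered 4 with normexp. The correlation between antibodies was 0.239 with loess and 0.230 with MAD scaling. The H3K36me3 median in the last part of ORFs differed by 0.19 with normexp, 0.076 with loess, 0.069 with quantile, 0.073 centred on low-transcribed lists and 0.067 after GC correction. The H14 downstream median reversed to -0.045 with normexp and was 0.16 with loess. The 5′ minus 3′ median for H14 was -0.087 with normexp, -0.079 with loess, -0.073 with quantile and -0.077 with MAD scaling, and for H3K36me3 -0.18 with normexp. Leaving out each array gave 0 to 59 H14 ORFs (59 without wild-type replicate 1, 11 higher and 48 lower), 0 to 1 H3K36me3 ORFs, 0 to 1212 H14 5′ minus 3′ ORFs (1212 without the same array), 0 to 15 for H3K36me3 and 0 for the interaction. It gave 0 to 15 H14 lists, 4 to 10 H3K36me3 lists and 2 to 4 H3K36me3 5′ minus 3′ lists. Correlations ran from 0.00318 to 0.231, last-part medians from 0.11 to 0.13 and downstream medians from 0.056 to 0.13. The 5′ minus 3′ medians ran from -0.078 to -0.061 for H14 and -0.11 to -0.09 for H3K36me3. A lone array of a group was then assumed to vary like the others, and for H3K36me3 leaving out either H14 array of a genotype gives the same fit. Camera's direction for H14 lists reversed past the threshold without rtr1 H14 replicate 2 for ribosomal proteins (adjusted p 1.65e-10), ribosome biogenesis (0.000958), glycolysis (0.000855), general stress (0.0442), proteasome (0.0332) and amino acid biosynthesis (0.0472). The last also reversed without batch 4 (8.02e-05), ribosomal proteins without wild-type H14 replicate 1 (0.0232) and mating genes without the library labelled wt H14 replicate 2 (0.00673). Over each array left out, these adjusted p ran from 5.88e-17 to 0.234 for ribosomal proteins, 9.22e-11 to 0.456 for ribosome biogenesis, 5.92e-07 to 0.940 for glycolysis, 0.00165 to 0.671 for general stress, 3.42e-05 to 0.861 for proteasome, 0.00364 to 0.581 for amino acid biosynthesis and 0.00673 to 0.834 for mating genes. Beyond the fewer arrays in some of these settings, the cause was not tested. Of the values for single named genes over all settings, 3456 kept their side of the threshold and 34 passed it, and of those for single lists 1768 kept it, 101 passed it and 43 lost it. Keeping probes that match several places was not run, for want of a genome sequence, nor a scan batch block apart from the replicate block. The number of arrays limits the precision.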

Other observations

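Chosen after the results were seen were the tests of the gene lists on the 5′ minus 3′ value, the values by H14 level and by region of a list, and the tests of the input at RTR1. Once their values were known, the test on the range of enrichment was given a second scaling and the test on input over glycolysis and histone ORFs a bootstrap interval.

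Over glycolysis and chaperone genes the H3K36me3 ratio of IP to input was shifted toward the 3′ end in rtr1, with differences in both channels. The 5′ minus 3′ value of the glycolysis and fermentation genes fell by a median of 0.54 over 13 genes in rtr1 (-0.61 and -0.39 in the 2 pairs; 12 lower in both; camera adjusted p 8.05e-08). It held with an estimated correlation (adjusted p = 0.0445). That of the heat shock chaperones fell by 0.35 over 23 genes (-0.50 and -0.35; 18 lower in both; adjusted p 4.67e-07; adjusted p = 0.0445 with an estimated correlation). These were the only 2 of 24 lists called, and both stayed called in all 26 other settings. With the replicate block 4 were called, with ribosomal proteins (-0.18) and cell wall genes (-0.25) added, both at an adjusted p of 0.0495 (in the fit without the block, adjusted p = 0.871 and 0.216 with an estimated correlation); without rtr1 H3K36me3 replicate 2, and with a normexp background correction, 4 were called too, 3 lower and 1, sporulation genes (median -0.03 over all arrays), higher by camera's direction. CDC19 (-1.42), the hexokinase gene HXK2 (-0.81) and the triosephosphate isomerase gene TPI1 (-0.68) led the first list and SSA2 (-1.16), SSA1 (-1.11) and the Hsp90 gene HSP82 (-0.73) the other; HXK2, TPI1, SSA1 and HSP82 were picked after their values were seen. Over glycolysis genes the H3K36me3 difference was 0.32 and 0.22 in the first part of the ORF, 0.57 and 0.51 in the middle and 0.82 and 0.68 in the last part. The IP channel differed by 0.20 and 0.22 in the first part and 0.47 and 0.52 in the last, and the input channel by -0.04 and 0.02 in the first and -0.25 and -0.09 in the last. Over the chaperone genes the difference was -0.05 and -0.03 in the first part and 0.39 and 0.25 in the last. There the IP channel differed by -0.10 and -0.04 in the first part and 0.14 and 0.16 in the last, and the input channel by 0.04 and 0.02 in the first and -0.15 and -0.06 in the last. At ADE17 the H3K36me3 value was lower in the first part in rtr1 (-0.82 and -0.80 in the pairs), near its wild-type level in the middle (0.13 and -0.04) and higher in the last part (0.82 and 0.62) and downstream (0.73 and 0.68). SHM2 had -0.30 and -0.58 in the first part and 0.86 and 0.82 in the last. The H14 5′ minus 3′ value of the 33 proteasome genes was also called lower (-0.27; -0.19 and -0.35 in the pairs; adjusted p 0.00526), but with an estimated correlation no H14 list was (smallest adjusted p = 0.512).

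The H3K36me3 difference in the last part of ORFs was largest in the ORFs with the highest H14. When ORFs were split into 10 equal classes by their mean H14 level, the median H3K36me3 difference in the last part was 0.08 and 0.08 in the lowest class (523 ORFs). It was 0.30 and 0.18 in the highest class (515 ORFs). In the replicate 1 pair it went up from each class to the next, while in the replicate 2 pair it was 0.05 in the third class and 0.07 in the fourth, below the lowest, and 0.12 in the ninth. In the first part of the ORF it was 0.08 and 0.09 in the lowest class and 0.00 and 0.01 in the highest, and in the middle part 0.02 and 0.06 against 0.14 and 0.07. No test was made over these values. Probes of the mitochondrial genome, which RNA polymerase II does not transcribe, had medians from -2.75 to -2.37 on 7 of the arrays and -0.60 on rtr1 H14 replicate 2.

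At RTR1 the input of the library labelled wt H14 replicate 2 lay between those of the other wild-type and the rtr1 arrays. An input wholly from rtr1 cells is argued against, since the value lay 1.76 above the highest of the 4 rtr1 arrays (log2). Uneven recovery of input DNA along the genome is a candidate, as 32 of 5657 other ORFs were at least as far below the other wild-type arrays on this array. Those ORFs are a small share, and the count does not explain why the gene deleted in rtr1 is as low as they are. The input of this library deviated from the mean of the other wild-type arrays with an SD of 0.725 over ORFs. The SD was 0.430 on rtr1 H14 replicate 2 of the same batch and 0.308 at most elsewhere. Those values are not like for like, since the wild-type mean behind them includes the library labelled wt H14 replicate 2. Its input correlated at 0.940 with that of rtr1 H14 replicate 2, which lowers the SD of the latter. An admixture of rtr1 cells cannot be told apart from this, since the probes nearer the stop codon lay 1.81 above those nearer the start codon, within the 95% range of such differences over 1303 other ORFs (-2.34 to 2.39), and no biological explanation was tested.

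The H14 differences of the 2 pairs were unrelated across ORFs. Uneven input in the batch of H14 replicate 2 is a candidate explanation, since the SD of the input difference over ORFs was 2.38 times that of the replicate 1 pair, and the H14 difference correlated with it at -0.732 in the replicate 2 pair and -0.466 in the other (input is part of both, which builds in some of this). A smaller range of enrichment on the library labelled wt H14 replicate 2 cannot be told apart from this: the difference of that pair went up with the H14 level of the replicate 1 pair (Spearman 0.261; slopes on that level 1.04 for wild type and 1.34 for rtr1), while the SD over ORFs, of which uneven input is a part, was 0.509 against 0.511. Scaling each array by its MAD, the test set beforehand, left 0.563 but decides nothing, since the wild-type array has the larger MAD (0.440 against 0.282) and dividing by it raises the correlation, and a scaling by the SD shared by odd and even probes moved almost nothing (ratio 0.997). A real difference in Ser5 phosphorylation that varied between cultures stays open and untested.

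H3K36me3 was higher over glycolysis and histone ORFs in both pairs, by 0.44 and 0.48 over 25 genes. For these 25 genes pooled, GC content is argued against, since the median was 0.40 after a GC correction and 0.46 before it. So is short ORF length, since 100% of 10000 length-matched random lists had a smaller median (highest 0.19). The histone genes were not tested alone in this way, and both lists were picked for their high medians in these data. Lower input over these ORFs in rtr1 cannot be told apart from more mark: the IP channel held 51.7% of the replicate 1 pair's difference (bootstrap 95% interval 29.0 to 70.8), with IP differences of 0.23 and 0.40 and input differences of -0.14 and -0.05. The interval comes from resampling the 25 genes as if they were independent, so it does not measure the spread between arrays. Fewer cross-linked or accessible fragments in the input, or a change in nucleosome occupancy, could produce the input part, and no array of total histone H3 was analysed here. An effect of RTR1 loss on the mark itself stays open and untested.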
